A study of Mus musculus with 9 samples.

How the data were processed

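Kidney RNA of AngII-treated mice was profiled by RNA-seq in 9 libraries, with 3 libraries in each of 3 genotype groups named in the sample titles as AngII, CDH16KO-AngII and GRPR-AngII. Per the labels' protocols, RNA was extracted with a Qiagen RNeasy kit and libraries were made from total RNA with a SMARTER mRNA-Seq kit. The submitters' processing notes name the genome builds GRCm38 and mm10. The aligner, the counting program and their settings are not given in the sources used here, nor is it given whether counting used strand.

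The deposited table listed 32593 genes with Ensembl identifiers, coordinates, annotation terms and, per the file headers, an FPKM value and a count for every library. The FPKM values deposited by the authors are scaled to transcript length and to the fragments of the library, and rounded to 2 decimals. The deposited counts were whole numbers, and no column belonged to a library outside the series. The value 4 was more frequent than 3 and than 5 in every library (in AngII library 1, 799 genes against 631 and 318). What makes the value 4 so frequent was not tested. The counts deposited by the authors were assumed to be expected counts, estimates already rounded to whole numbers, and the tests below treat them as counts of reads. Of the gene identifiers, 32494 occurred in the GENCODE M21 annotation of GRCm38, and 91.1% of these had the same start and end there. Coordinates are given as deposited, on that build.

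The design had been written for FPKM values with limma, and named edgeR in case the table held counts. The quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 was the main test, with TMM scaling, library sizes equal to the column totals, and all 9 libraries in 1 fit with 1 coefficient per group and no block. Genes with an FPKM of at least 1 in at least 3 libraries were tested, which left 12507. Benjamini-Hochberg adjusted p under 0.05 was the threshold for a call. Standard errors of log2 fold changes were obtained from the fold change and its F statistic. CPM values are counts scaled to 1e+06 per library after TMM scaling. A count of 0 allows up to 3 counts, which was 0.0496 to 0.0737 CPM before scaling. Comparisons of single genes outside that test used an exact two-sided permutation test, whose smallest p with 3 against 3 libraries is 0.1.

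A set of 36 gene lists (pathways, kidney and immune cell types, sex and clock genes) was tested with camera of limma 3.58.1 and a preset correlation of 0.01, adjusted over the 33 lists with at least 5 tested members. Camera with an estimated correlation and fry were run beside it. Named genes followed a rule. It took Sting1, Grpr, Cdh16 and Acsl4. It took up to 10 largest rises and falls in log2(FPKM + 1) among called genes with non-overlapping ranges, a mean FPKM of at least 2 in 1 group and no predicted-gene name. It filled up to 5 per direction by smallest p. It also took up to 4 members of smallest p from every called list and from the interferon, inflammation, ferroptosis, antioxidant, fibrosis and injury lists. The table had no row under the symbol Grpr, so that gene is not analysed here. Some genes that the rule takes are not reported here. Annotation enrichment was planned only for 20 or more calls in a direction and was not run. Groups, tests, lists, the naming rule and most alternatives were fixed before the data were examined. The KEGG pathway test over the deposited annotation, the counts divided by 4 and the fit without mitochondrial genes were added after seeing the data.

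The tests were tested on simulated data: negative binomial counts were drawn for the 12507 genes from their means, dispersions and library sizes, with 67, 67 and 66 genes changed 1.5-fold, 2-fold and 4-fold in 1 group. For CDH16KO-AngII against AngII, edgeR recovered 10.4% of genes changed 1.5-fold, 46.3% of those changed 2-fold and 98.5% of those changed 4-fold, with 5 false calls among 108. For GRPR-AngII against AngII the shares were 8.96%, 44.8% and 92.4%, with 7 false calls among 104. On the same simulated CDH16KO-AngII counts DESeq2 1.42.0 made 169 calls, 37 of them false. Camera called 2 lists when the fatty acid oxidation list was shifted and 0 lists when nothing was. Genes were drawn independently of each other, so these draws do not test camera where the genes of a list are correlated.

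Replicates were compared before averaging. The chi-square per gene between libraries of 1 group lay between 74.2 and 366, far above sampling noise, so no library was counted as a copy of another. The labels do not say that the libraries came from separate animals, and p-values measure the spread between these libraries. Shared sequence was searched with BLAST+ 2.17.0 in the GENCODE M21 transcripts, taking 95% identity over 50% of the longest transcript as shared. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Alternatives were other filters, scalings, pseudocounts, tools (DESeq2, limma), a block for the replicate number, fits of 2 groups only and leaving out each library in turn.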

Results

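RNA-seq was done on kidneys of mice treated with AngII (angiotensin II, a peptide hormone that raises blood pressure). The series title places the work in hypertension-associated kidney disease and names STING, an innate immune adaptor that senses cytosolic DNA signals, and ACSL4, an enzyme that loads polyunsaturated fatty acids onto coenzyme A. The AngII group carried a floxed Tmem allele without Cre. The CDH16KO-AngII group carried the same floxed allele with Cre under the promoter of Cdh16, a cadherin of kidney tubule epithelium. The GRPR-AngII group carried that Cre with a floxed GRPR allele. Each group had 3 libraries. All groups received AngII, so the effect of AngII itself is not analysed here, and no Cre-negative floxed GRPR group was compared. Totals were 40731748 to 60449117 counts per library, and 11456 to 12276 genes reached an FPKM of 1. Mitochondria-coded genes took 16.1% to 26.4% of the counts. Their mean share was 18.7% ± 2.40 in AngII, 21.98% ± 5.29 in CDH16KO-AngII and 20.9% ± 3.15 in GRPR-AngII (SD, n = 3 per group).

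The floxed gene was examined first. The labels write only Tmem, and the series title names STING, whose gene Sting1 was formerly called Tmem173 (ENSMUSG00000024349). Sting1 stood at 4.62, 1.77 and 5.33 CPM in the AngII libraries, a mean of 3.904 ± 1.88 (SD, n = 3). It stood at 2.15 ± 0.10 CPM in CDH16KO-AngII and at 2.82 ± 0.127 CPM in GRPR-AngII (SD, n = 3). The CDH16KO-AngII libraries lay within the AngII range, because AngII library 2 was below all of them (exact two-sided permutation p = 0.4). They lay below all GRPR-AngII libraries (exact two-sided permutation p = 0.1, the smallest that 3 against 3 libraries allow). With the filter lowered to an FPKM of 0.1, edgeR gave Sting1 a log2 fold change of −0.86 in CDH16KO-AngII against AngII (SE 0.36, adjusted p = 0.604), −0.45 in GRPR-AngII against AngII (SE 0.35, adjusted p = 0.857) and 0.41 in GRPR-AngII against CDH16KO-AngII (SE 0.36, adjusted p = 0.982). These values do not settle whether the gene was deleted, and which exons are floxed is not given in the sources used here. Cdh16, whose name the group title carries, was at 659 ± 52.9 CPM in CDH16KO-AngII and 713 ± 83.1 CPM in AngII (log2 fold change −0.11, edgeR adjusted p = 0.836). Acsl4 was at 16.5 ± 3.91 CPM in CDH16KO-AngII, 16.9 ± 2.11 CPM in GRPR-AngII and 19.8 ± 0.291 CPM in AngII, and was not called in any comparison (edgeR adjusted p = 0.678 for CDH16KO-AngII and 0.796 for GRPR-AngII against AngII).

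CDH16KO-AngII was compared with AngII, Cre-positive with Cre-negative mice of the same floxed allele, so the groups differ in the presence of Cre as well as in any deletion. Other genetic differences between these groups were not excluded. The second of 2 annotated Nnt models took 93.5%, 95.8% and 0% of their summed counts in the AngII libraries. In the CDH16KO-AngII libraries it took 34.1%, 44.0% and 0%. Vnn1, a pantetheinase, stood at 34.3 ± 9.11 CPM against 101 ± 15.3 CPM, a 2.93-fold fall (SD, n = 3 per group). Acox2, the peroxisomal oxidase of branched chains and bile acid intermediates, fell 2.48-fold from 77.1 ± 15.96 to 31.1 ± 6.87 CPM. Hacl1, the lyase of peroxisomal alpha-oxidation, fell 2.74-fold to 13.2 ± 1.34 CPM. Acot2, a mitochondrial acyl-CoA thioesterase, fell 1.82-fold to 18.7 ± 2.002 CPM, and Cyp4a12b, a fatty acid hydroxylase, fell 7.98-fold to 2.83 ± 0.933 CPM. The glycosyltransferase gene A4galt fell 1.99-fold. The edgeR adjusted p of these 6 genes lay between 0.0199 and 0.046. Col6a6, a collagen VI chain, rose 13.6-fold from 2.01 ± 0.159 to 27.4 ± 8.28 CPM, and Hddc3, a phosphohydrolase gene, rose 4.41-fold from 5.86 ± 0.731 to 25.9 ± 8.23 CPM. The histone genes Hist1h2bq and H2bc13 rose 8.28-fold and 9.86-fold to 6.48 ± 2.43 and 1.64 ± 0.852 CPM. The edgeR adjusted p of these 4 rises lay between 0.0033 and 0.0281. Col6a6 also stood at 11.3 ± 4.68 CPM in GRPR-AngII, 5.6-fold above AngII without passing the threshold there (edgeR adjusted p = 0.107). Col6a6 overlaps a gene on the opposite strand, and the strand of counting is not stated. Reads of several others cannot be assigned with certainty. Cyp4a12b matched Cyp4a12a over 100% of its transcript, Acot2 matched Acot1 over 58%, and both histone genes matched Hist1h2br over 99.4% to 100%. Hacl1 and Hddc3 shared 53% and 70.9% of their transcripts with overlapping genes.

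**Figure D1:**
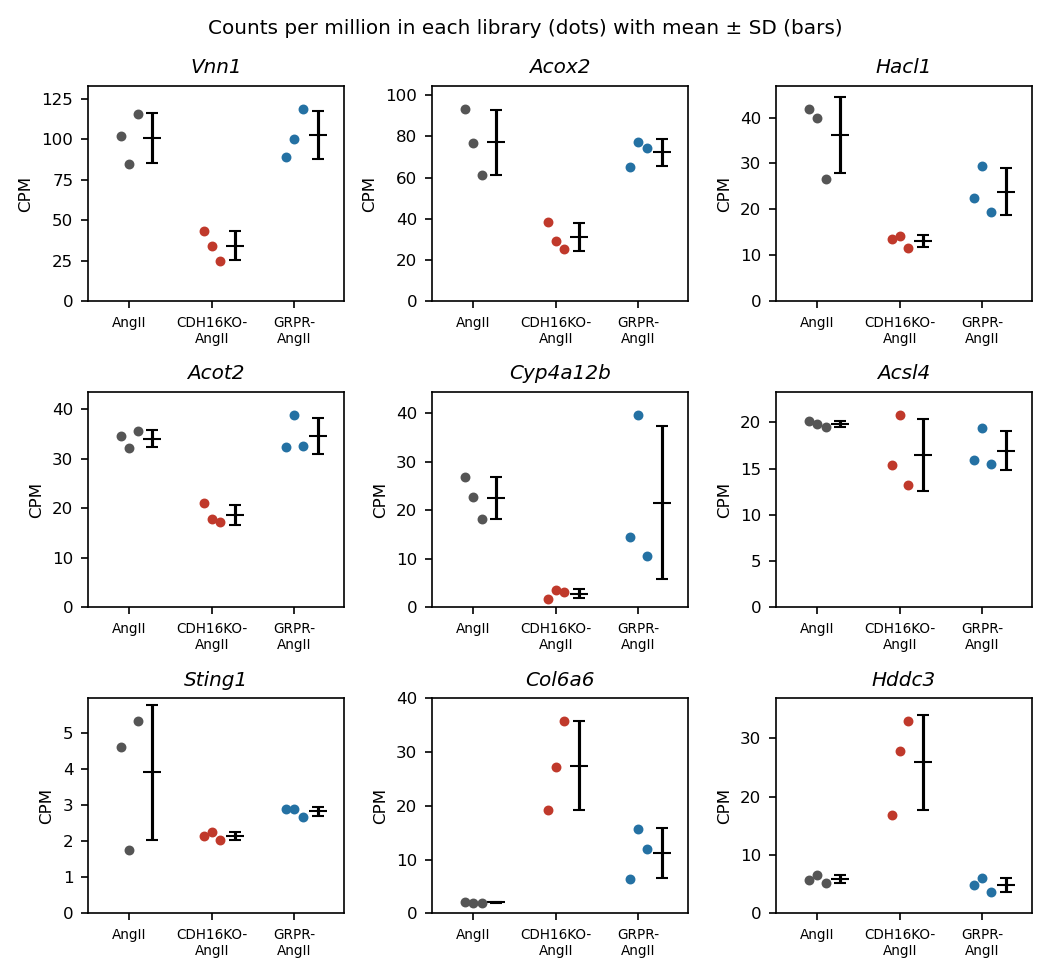
CPM (vertical axis) of 9 genes in the 3 groups (horizontal axis), with 1 dot per library and a bar for the mean ± SD of 3 libraries. Vnn1 lay at 34.3 CPM on average in CDH16KO-AngII, 101 CPM in AngII and 103 CPM in GRPR-AngII, while 1 AngII library of Sting1 lay below every CDH16KO-AngII library.

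In all, edgeR called 21 of 12507 genes, 13 higher and 8 lower in CDH16KO-AngII, and 1057 genes had an unadjusted p under 0.05 where chance gives 625. Ranges of the 3 against 3 libraries did not overlap for 12.2% of genes, where chance gives 10%. Of the 21, 10 had predicted-gene, clone or pseudogene names. Tsen54, a tRNA splicing gene, had the smallest p among the higher genes that met the naming rule and did not pass the threshold (edgeR adjusted p = 0.0564). The Vnn1, Acox2, Hacl1, Acot2, Col6a6 and Hddc3 genes lie on GRCm38 at chromosome 10 (23894688 to 23905343), chromosome 14 (8225511 to 8259353), chromosome 14 (31598730 to 31641257), chromosome 12 (83987861 to 83993873), chromosome 9 (105687809 to 105828160) and chromosome 7 (80343104 to 80350547). The count was 0 without AngII library 1, 3 without AngII library 2, 3 without CDH16KO-AngII library 3 and 12 without GRPR-AngII library 1. It was 42 without CDH16KO-AngII library 1 and 35 without CDH16KO-AngII library 2, and DESeq2 called 210. Of the 9 fits that left out 1 library, Col6a6 was called in 8 (all but that without AngII library 1), Hist1h2bq in 6, Vnn1 and Hddc3 in 5, Hacl1 in 4, H2bc13 in 3, Acox2, Acot2 and Cyp4a12b in 2 and A4galt in 0. None of the 10 was called without AngII library 1. A block for the replicate number ended the calls of A4galt, Acot2 and H2bc13.

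The fatty acid oxidation list was lower as a group in CDH16KO-AngII. Of its 36 tested members, 35 had a negative log2 fold change, with a median of −0.59. Over all genes 2 members were called lower, Acox2 and Acot2, and 22 were lower when adjusted over the list alone. Beyond these 2, the omega-hydroxylase gene Cyp4a10, which matched Cyp4a31 over 75.5% of its transcript, had a log2 fold change of −1.70 (SE 0.33), Ehhadh of peroxisomal beta-oxidation −1.56 (SE 0.33) and the carnitine palmitoyltransferase gene Cpt2 −0.72 (SE 0.14). Ppara, the receptor that regulates many of these genes, had −0.24 (SE 0.32), and Ppargc1a was the member with a positive value, 0.11 (SE 0.21). Ehhadh, Ppara and Ppargc1a were named outside the naming rule. They were not searched for shared sequence or followed over the other settings. The list was called by camera with the preset correlation (adjusted p = 5.52e-35) and was not called with an estimated correlation (p = 0.00485 by camera, adjusted p = 0.16). Mean log2 CPM over the list was 5.99 ± 0.29 in CDH16KO-AngII, 6.86 ± 0.06 in AngII and 6.68 ± 0.29 in GRPR-AngII (SD, n = 3). All CDH16KO-AngII libraries lay below all AngII libraries, which gives the smallest exact permutation p of 0.1. Within CDH16KO-AngII the list mean was 5.93, 6.30 and 5.73 in libraries 1, 2 and 3. It went with the mean of the proximal tubule markers (8.38, 8.93 and 8.35) and against the mitochondrial share (23.4%, 16.1% and 26.4%).

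Antioxidant genes were also lower as a group. The glutathione and NRF2 list had 28 of 31 members with a negative log2 fold change and a median of −0.41 (camera adjusted p = 3.15e-12, and adjusted p = 0.367 with an estimated correlation). No member was called over all genes, and 8 were lower when adjusted over the list alone. Gsta1 was called in 6 other settings, among them DESeq2, the replicate block and the fit without CDH16KO-AngII library 2, and Nqo1 in 3, among them the fit without CDH16KO-AngII library 1. The glutathione transferase gene Gsta1 stood at 4.14 ± 1.70 against 14.5 ± 1.68 CPM and Gsta2 at 194 ± 57.2 against 379 ± 31.8 CPM. The quinone reductase gene Nqo1 stood at 30.8 ± 8.07 against 62.6 ± 12.6 CPM and Mgst1 at 48.8 ± 8.28 against 75.8 ± 9.36 CPM. Reads of Gsta1 and Gsta2 cannot be assigned with certainty, as Gsta2 matched Gsta1 over 100% of its transcript. In CDH16KO-AngII the mean log2 CPM of the list was 6.98, 7.21 and 6.72 in libraries 1, 2 and 3. It went with the mean of the proximal tubule markers (8.38, 8.93 and 8.35) and against the mitochondrial share (23.4%, 16.1% and 26.4%). The fatty acid oxidation list did the same. Library 2 had the highest marker mean and the lowest mitochondrial share of all libraries. Its antioxidant mean still lay below that of every AngII and GRPR-AngII library (7.29 to 7.57). That is 1 library, so the fall of the antioxidant list was not set apart from either. Leaving out any 1 library except GRPR-AngII library 2 gave 6 to 14 called lists in place of 2. Other splits of the 6 libraries called up to 18 lists, so the number of called lists does not exceed that of other groupings.

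**Figure D2:**
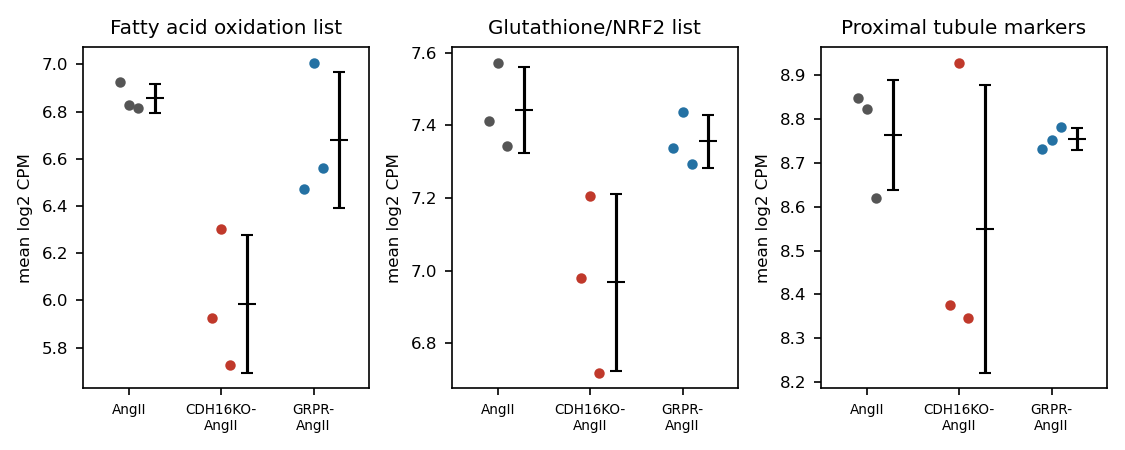
Mean log2 CPM over the members of 3 gene lists (vertical axes) in the 3 groups (horizontal axis), with 1 dot per library and a bar for the mean ± SD of 3 libraries. The fatty acid oxidation mean was 5.99 in CDH16KO-AngII, 6.86 in AngII and 6.68 in GRPR-AngII.

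Lists of immune and fibrotic genes were not called in this comparison. The interferon and STING response list had 19 of 30 members negative and a median of −0.14. Its members of smallest p were Trim30a, at 3.94 ± 0.645 against 6.52 ± 1.68 CPM, Irf3, at 93.7 ± 16.9 against 71.8 ± 8.83 CPM, Gbp2 and Gbp3. The inflammatory cytokine list had a median of 0.02, and Il34, Ccl5, Tnfaip2 and Cx3cl1 had log2 fold changes of 0.64, −0.90, 0.50 and −0.28. The extracellular matrix and fibrosis list had 19 of 23 members positive and a median of 0.21, with Acta2 at 0.56, Sparc at 0.45, Loxl2 at 0.52 and Col6a3 at 0.58. Acta2 was at 0.26 without CDH16KO-AngII library 1 and Col6a3 at 0.26 without CDH16KO-AngII library 3. The tubular injury list had a median of −0.10, with the fibrinogen genes Fga at −1.46 and Fgg at −1.69, Krt8 at −0.36 and Tnfrsf12a at 0.49. The ferroptosis and iron list had a median of −0.08, with Cbs at −0.47, Map1lc3a at −0.32, Slc40a1 at −0.36 and Lpcat3 at −0.23. None of these members passed the threshold. Over the 3 comparisons, the rule took 124 values of genes that were not called, and leaving out 1 library moved 63 of them by over 1.5 times. In CDH16KO-AngII against AngII these also included Cdh16, Acsl4, Irf3, Gbp2, Gbp3, Ccl5, Tnfaip2, Tnfrsf12a, Map1lc3a, Slc40a1 and Lpcat3.

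The remaining lists were not called either, and the camera adjusted p of the 31 uncalled lists lay between 0.0556 and 0.969. Among tubule segments, median log2 fold changes were −0.17 for proximal tubule markers, 0.21 for loop of Henle and distal convoluted tubule markers, −0.10 for collecting duct markers and 0.05 for distal sodium and water transport genes. Other kidney cell types had medians of 0.13 (podocyte), 0.11 (endothelial), 0.18 (stromal, pericyte and smooth muscle) and −0.46 (urothelium and renal pelvis). Immune and blood lists had medians of −0.29 (macrophage and dendritic cell), −0.53 (T and NK cell), −0.11 (B and plasma cell), −0.01 (MHC and antigen presentation), −0.05 (complement and acute phase) and −0.27 (erythroid). Metabolic lists had medians of −0.15 (cholesterol and lipid synthesis), −0.06 (nuclear-coded oxidative phosphorylation), 0.29 (mitochondria-coded oxidative phosphorylation) and −0.17 (adipocyte markers). Medians were 0.11 for heat shock and unfolded protein genes, 0.05 for apoptosis, necroptosis and pyroptosis genes, −0.21 for proliferation genes and 0.11 for immediate early genes. They were 0.00 for circadian clock genes, −0.05 for renin-angiotensin and vasoactive genes, 0.03 for Y-linked and male-biased genes and −0.14 for female-biased genes. The NADPH oxidase, neutrophil and adrenal lists had only 3, 2 and 3 tested members, with medians of −0.14, −0.08 and −0.10.

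GRPR-AngII was compared with AngII, a comparison in which the floxed allele and the presence of Cre both differ. No gene was called by edgeR among 12507, where 843 had an unadjusted p under 0.05 against 625 by chance and the smallest adjusted p was 0.107. DESeq2 called 54 genes, and limma on log2 FPKM called 0. Ranges did not overlap for 14.05% of genes, where chance gives 10%. The count was 2 without AngII library 3 and 1 without GRPR-AngII library 1. The genes of smallest p among those higher that met the naming rule were the apolipoprotein genes Apoc3, at 23.7 ± 4.59 against 8.53 ± 1.36 CPM, and Apoa4, at 24.6 ± 7.499 against 7.66 ± 0.887 CPM, with Misp3, the peptidase gene Dpp7 and Tmigd1, at 235 ± 7.87 against 133 ± 8.62 CPM (SD, n = 3). Those lower included Vgll4, at 9.91 ± 1.497 against 19.5 ± 4.20 CPM, Ppp1r10, Erf and Pck1, the gluconeogenic carboxykinase, with a log2 fold change of −1.61 (SE 0.36). None passed the threshold (edgeR adjusted p from 0.173 to 0.54).

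No list was called in that comparison, with the smallest camera adjusted p at 0.0766. Over the other settings run, 0 to 8 lists were called. The fatty acid oxidation list had 27 of 36 members negative and a median of −0.12, and the antioxidant list had a median of −0.01, with Gsta1 at −1.32, Nfe2l2 at −0.42, Gsta2 at −0.41 and G6pdx at −0.22. The interferon and STING list had a median of −0.03, with Rsad2 at 0.61, Irf3 at 0.25, Usp18 at −0.37 and Isg15, which shared 63.8% of its transcript with another gene, at 0.43. The inflammatory list had a median of −0.11, with Nfkb2 at −0.33, Relb at −0.36, Tnfaip2 at 0.41 and Il34 at 0.39. The fibrosis list had 19 of 23 members positive and a median of 0.24, with Col4a1 at 0.51, Col6a3 at 0.76, Thbs1 at −0.53 and Loxl1 at 0.64. The injury list had a median of −0.09, with Krt8 at −0.40, Egf at −0.53, Spp1 at −0.49 and Clu at −0.72, the last 2 at −0.28 and −0.23 without AngII library 3, and Spp1 also at −0.28 without GRPR-AngII library 3. The ferroptosis list had a median of 0.03, with Ftl1, near-identical to a pseudogene, at 0.50, Slc40a1 at −0.38, Prnp at −0.47 and Acsl3 at −0.33. Leaving out 1 library also moved by over 1.5 times the values of Gsta2, G6pdx, Irf3, Usp18, Isg15, Relb, Tnfaip2, Il34, Thbs1, Loxl1, Slc40a1 and Acsl3. Fry, which asks whether the genes of a list move one way on balance, called the circadian clock list (15 of 20 members negative, adjusted p = 0.0121).

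GRPR-AngII was compared with CDH16KO-AngII, both Cre-positive and differing in the floxed allele. Vnn1 was 2.99-fold higher in GRPR-AngII, at 103 ± 14.9 against 34.3 ± 9.11 CPM, and Acot2 was 1.85-fold higher (SD, n = 3). Tmigd1, an immunoglobulin-domain membrane gene, was 2.71-fold higher at 235 ± 7.87 against 86.9 ± 20.4 CPM, the growth factor gene Fgf1 2.24-fold higher at 189 ± 23.1 against 84.5 ± 7.24 CPM, and Fbp2, a fructose-bisphosphatase, 2.22-fold higher at 17.2 ± 1.08 against 7.75 ± 1.51 CPM. Hddc3 was 5.32-fold lower, Hist1h2bq 9.34-fold lower and H2bc13 11.02-fold lower in GRPR-AngII. The edgeR adjusted p of these 8 genes lay between 0.0117 and 0.0358. H2bc12, lower at 0.625 ± 0.197 against 4.30 ± 2.17 CPM, did not pass the threshold (edgeR adjusted p = 0.0688). H2bc12 matched Hist1h2bg over 81.7% of its transcript, and Fgf1 overlaps opposite-strand genes. Each of the 8 calls was lost without GRPR-AngII library 1, without GRPR-AngII library 3 and without CDH16KO-AngII library 3. A block for the replicate number also ended the calls of Vnn1, Acot2 and H2bc13.

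In this comparison edgeR called 18 genes, 7 higher and 11 lower in GRPR-AngII, and 780 had an unadjusted p under 0.05. Ranges did not overlap for 9.96% of genes, where chance gives 10%. The count was 0 without GRPR-AngII library 1, 6 without GRPR-AngII library 2, 5 without GRPR-AngII library 3, 2 without CDH16KO-AngII library 3 and 50 without CDH16KO-AngII library 1. A fit of these 2 groups alone called 9 genes and DESeq2 called 175, and limma on log2 TPM called 11, with 1 higher and 10 lower.

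By camera 11 lists were called in this comparison, 9 higher and 2 lower in GRPR-AngII, and with an estimated correlation 0 were called. The fatty acid oxidation list had 32 of 36 members positive and a median of 0.45 (camera adjusted p = 6.62e-29, and adjusted p = 0.146 with an estimated correlation), with Acot1 at 74.6 ± 40.5 against 13.8 ± 7.22 CPM and Acox2 at 72.4 ± 6.48 against 31.1 ± 6.87 CPM. In it 1 member was higher over all genes and 17 when adjusted over the list alone. The antioxidant list had 28 of 31 members positive and a median of 0.40, with 0 called over all genes and 2 when adjusted over the list alone (camera adjusted p = 7.77e-11, and adjusted p = 0.227 with an estimated correlation). Its members of smallest p were Nqo1 at 1.03, Gstp1 at 0.81, Mgst1 at 0.58 and Hmox1 at 1.22, where Gstp1 matched Gstp2 over 86.1% of its transcript and Hmox1 was at 0.49 without GRPR-AngII library 2. On leaving out 1 library the medians ran from 0.37 to 0.72 for fatty acid oxidation and from 0.25 to 0.49 for the antioxidant list. Other splits of these 6 libraries called up to 19 lists, so here too the number of called lists does not exceed that of other groupings.

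Smaller shifts were called for 7 more lists that were higher. The complement and acute phase list had a median of 0.30, with Fga at 1.46, Fgg at 2.35, Cfi at 1.23 and Cd55 at 0.33. The proximal tubule list had a median of 0.16, with Cyp7b1 at 1.45, Slc22a12 at 0.69, Slc34a1 at 0.50 and Slc13a1 at 0.61. The adipocyte list had a median of 0.28, with Lipe at 0.59, Thrsp at 0.88, Car3 at 0.81 and Acsl1 at 0.44. The nuclear-coded oxidative phosphorylation list had a median of 0.12, which was −0.013 on quantile-normalized values, with Uqcrb at 0.31, Sdha at 0.59, Ndufa4 at 0.40 and Cox5a at 0.41. The ferroptosis and iron list had a median of 0.06, with Cbs at 0.56, Hmox1 at 1.22, Ftl1 at 0.47 and Gpx4, which matched a pseudogene over 73.7% of its transcript, at 0.37. The macrophage and dendritic cell list had a median of 0.26, with C1qb at 0.50, Aif1 at 0.58, C1qa at 0.49 and H2-Aa at 0.37. The Y-linked and male-biased list had a median of −0.03 although its mean was 0.15 and camera gave it as higher, with Cyp7b1 at 1.45, Acsm3 at 1.08, Kap at 0.54 and Slc7a13 at 0.38. On leaving out 1 library, in the order given, these medians ran from 0.22 to 0.62, 0.04 to 0.48, 0.23 to 0.46, 0.06 to 0.24, 0.01 to 0.19, 0.13 to 0.55 and −0.09 to 0.29, and over all settings run the calls were lost in 2, 5, 3, 5, 5, 6 and 7. Leaving out 1 library moved by over 1.5 times the values of Fga, Fgg, Cd55, Acsl1, Sdha, Ndufa4, Cox5a, Acsm3, Kap, Slc7a13, all 4 macrophage genes and Car3, which was at 0.23 without GRPR-AngII library 1. With an estimated correlation the adjusted p of these 7 lists lay between 0.146 and 0.866. Their camera adjusted p lay between 2.86e-05 and 0.0323.

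The loop of Henle and distal convoluted tubule list was lower in GRPR-AngII than in CDH16KO-AngII (16 of 21 members negative, median −0.28), with Pvalb at −0.92, Kcnj1 at −0.38, Cldn10 at −0.46 and Slc12a1 at −0.65. The circadian clock list was lower too (19 of 20 negative, median −0.23), with Usp2 at −0.44, Hlf at −0.45, Per3 at −0.67 and Fkbp5 at −0.46, which was 0.068 with library weights. On leaving out 1 library their medians ran from −0.32 to −0.15 and from −0.31 to −0.20, and each lost its call in 4 settings. Adjusted p with an estimated correlation was 0.346 and 0.227 for these lists, and camera adjusted p was 0.00784 and 0.0249. Fry called the circadian list (adjusted p = 0.00535) and the adipocyte list (adjusted p = 0.0431). The interferon and STING list was not called (median 0.13), with Trim30a at 0.78, Rsad2 at 0.55, Irf1 at 0.56 and Gbp3 at 0.40. Nor was the inflammatory list (median −0.09), with Nfkb2 at −0.51, Cxcl16 at −0.34, Ccl5 at 0.87 and Ccl12 at 0.96. The fibrosis list had a median of 0.04, with Thbs1 at −0.63, Dcn at 0.45, Acta2 at −0.41 and Col4a1 at 0.30. The injury list had a median of −0.04, with Egf at −0.44 and Plin2 at 0.46. Leaving out 1 library moved by over 1.5 times the values of Pvalb, Cldn10, Slc12a1, Usp2, Hlf, Per3, Fkbp5, Irf1, Cxcl16, Ccl5, Ccl12, Thbs1, Dcn, Acta2, Col4a1, Egf, Plin2 and Gbp3, which was at 0.10 without GRPR-AngII library 1.

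A test of any difference among the 3 groups called 19 genes by edgeR, 16 of them also called for CDH16KO-AngII against AngII. Across the pairwise comparisons 14 genes were called in CDH16KO-AngII against both other groups, 10 higher and 4 lower in CDH16KO-AngII. The 4 lower ones were Vnn1, Acot2, Zfp429, a zinc finger gene at 0.334 ± 0.159 against 3.57 ± 1.16 CPM in AngII, and 1810034E14Rik, the last 2 named after their values were seen. These comparisons share the CDH16KO-AngII libraries. Independent lists of these sizes would share 0.0114 higher and 0.00448 lower genes, a value that leaves out the shared libraries. The 20 simulated sets without effects shared 0, a value that leaves out the effects, so neither shows how large the overlap would be by chance. Part of it may come from the shared libraries, which are too few to be split.

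Log2 fold changes of CDH16KO-AngII and GRPR-AngII, each against the same AngII libraries, had a Pearson r of 0.508 across 12507 genes, which are not independent replicates. Unchanged simulated groups gave 0.494 ± 0.0261 (SD over 20 simulated sets). Genes were drawn independently here too, so the simulated SD leaves out correlation between genes. The covariance was 0.0676 against a simulated 0.0492 ± 0.00533, a difference of 0.0184. Signs matched for 71.7% of genes against a simulated 66.6%. The 3 shared controls cannot be split, so part of any excess may come from them.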

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

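The counts divided by 4, the fit without mitochondrial genes and the pathway test were chosen after seeing the data. For CDH16KO-AngII against AngII, the 21 calls became 45 without a filter, 3 with a mean FPKM of at least 5, 210 with DESeq2 and 1133 with library weights in limma, and 0 to 42 on leaving out each library in turn (0 without AngII library 1). For GRPR-AngII against AngII, the 0 calls became 1 without a filter, 54 with DESeq2 and 0 to 2 on leaving out a library, and 0 under all other settings tried. For GRPR-AngII against CDH16KO-AngII, the 18 calls became 45 without a filter, 5 with a mean FPKM of at least 5, 175 with DESeq2, 11 with limma on TPM, 164 with library weights, 9 with only the 2 groups, and 0 to 50 on leaving out a library (0 without GRPR-AngII library 1). Among all 3 groups, the 19 calls became 56 without a filter, 6 with a mean FPKM of at least 5, 258 with DESeq2, 472 with library weights, and 7 to 51 on leaving out a library. Fewer or more genes tested is part of the filter settings; for the other settings the cause was not tested, though DESeq2 made 37 false calls among 169 on simulated counts. All FPKM settings with limma change the tool and the values together.

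Gene lists called in CDH16KO-AngII against AngII went from 2 to 10 with the filter at 0.1, 15 without a filter, 5 with limma without a trend, 10 with library weights, 11 with only the 2 groups, 0 with an estimated correlation, 0 with fry and 2 to 14 on leaving out a library. In GRPR-AngII against AngII they went from 0 to 1 without a filter, 2 with limma on FPKM at each pseudocount (1, 0.5 and 0.1), 3 on TPM, 1 on quantile-normalized values, 2 without a trend, 7 with library weights, 4 with only the 2 groups, 1 with fry and 0 to 8 on leaving out a library. In GRPR-AngII against CDH16KO-AngII they went from 11 to 20 without a filter, 5 on quantile-normalized values, 0 with an estimated correlation, 2 with fry and 8 to 15 on leaving out a library. The fatty acid oxidation list in CDH16KO-AngII against AngII kept its direction in every setting, with a median of −0.83 to −0.52 on leaving out a library, and lost its call only with an estimated correlation and with fry (adjusted p = 0.16 and 0.0687, range over the settings 6.93e-45 to 0.16). The antioxidant list also kept its direction and lost its call only in these (adjusted p = 0.367 and 0.158, range 1.45e-15 to 0.367). A log2 change of at least 1 gives no value for lists. In GRPR-AngII against AngII the median of all genes was −0.15 with limma on TPM, −0.06 with limma on FPKM and −0.01 with edgeR.

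The replicate numbers were not taken as pairing the libraries: same-number libraries had deviations that correlated over 0.1 in 6 of 9 pairs, at 0.11 to 0.24 for numbers 2 and 3 and at −0.10 to 0.09 for number 1, and 6 of 9 libraries were closest to their own number. With a replicate block, calls were 26, 0 and 13 in the 3 comparisons and 22 among all groups, and lists called were 10, 3 and 13. Among named genes the block added calls of Gsta1, Tsen54 and Fga in CDH16KO-AngII against AngII and of Fga in GRPR-AngII against CDH16KO-AngII, and ended those of A4galt, Acot2 and H2bc13 in the first and of Vnn1, Acot2 and H2bc13 in the last. The log2 fold changes of Sting1 with the block were −0.79, −0.38 and 0.40.

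Direction reversed for the nuclear-coded oxidative phosphorylation list in GRPR-AngII against CDH16KO-AngII on quantile-normalized values (median −0.013), for Acsl4 there without CDH16KO-AngII library 1 (−0.0022) or 3 (−0.096) or GRPR-AngII library 2 (−0.068), and for Fkbp5 there with library weights (0.068); the cause was not tested. Among other values of named genes and lists, 3589 kept their sign and their side of the threshold, 188 lost the threshold and 75 passed it. Keeping both does not mean an unchanged value. Leaving out 1 library moved 63 of the 124 uncalled values of named genes by over 1.5 times. Over the settings run, Sting1 ranged from −1.21 to −0.57, −0.82 to −0.18 and 0.35 to 0.43 in the 3 comparisons, and the correlation of the comparisons from 0.431 to 0.681. At 40731748 to 60449117 counts per library, Sting1 stayed below the filter, and 2-fold changes were recovered in 46.3% of simulated genes.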

Other observations

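The tests of the proximal tubule share, of a chromosome segment, of the Nnt models and of other splits for the fatty acid oxidation median were chosen after the results were seen, as was the pathway test. In KEGG pathways annotated in the deposited table, added after seeing the data, 40 of 299 were called by camera in CDH16KO-AngII against AngII, 39 of them lower, and 0 with an estimated correlation. Fatty acid degradation had 39 of 40 tested genes negative and a median log2 fold change of −0.48, PPAR signaling 47 of 58 and −0.28, and peroxisome 59 of 75 and −0.24. Ferroptosis was lower (26 of 35 negative, median −0.06, camera adjusted p = 0.0425) and ECM-receptor interaction higher (32 of 45 positive, median 0.17, camera adjusted p = 0.0389), although the ferroptosis and fibrosis lists were not called. In GRPR-AngII against AngII 14 pathways were called, with ribosome genes higher (110 of 130 positive, median 0.17) and proximal tubule bicarbonate reclamation and fatty acid degradation lower (medians −0.40 and −0.18, the latter with 34 of 40 negative), and in GRPR-AngII against CDH16KO-AngII 26 were called, all higher, and with an estimated correlation 0 in each. Leaving out 1 library gave 29 to 47, 7 to 22 and 9 to 51 pathways in these comparisons, with 7 without AngII library 1 and 22 without GRPR-AngII library 1 in the second, and 17, 51 and 9 without CDH16KO-AngII library 1, 2 and 3 in the third. Other splits of the same 6 libraries called up to 77, 60 and 49 pathways, and at least as many as the real one in 4, 7 and 5 of 10 splits.

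Hemoglobin genes took 77.5 to 1886 CPM, with the lowest values in AngII library 1 and GRPR-AngII library 1 (139 CPM). All libraries expressed the Y-linked gene Ddx3y, at 28.2 to 29.8 CPM as group means. Among replication-dependent histone genes that were named by the rule, H2bc12 stood at 4.30 ± 2.17 CPM in CDH16KO-AngII and 0.625 ± 0.197 CPM in GRPR-AngII.

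Fatty acid oxidation genes were lower in CDH16KO-AngII than in AngII by camera with the preset correlation, and were not called with an estimated correlation (adjusted p = 0.16) or by fry (adjusted p = 0.0687). The median of proximal tubule markers outside the list lay 0.42 above that of the list (95% interval 0.24 to 0.75 from a bootstrap over genes). These markers thus fell less than the list in these libraries. The interval leaves out the spread between libraries, so it cannot decide about fewer proximal tubule cells as the whole cause. Within CDH16KO-AngII the mean of the fatty acid oxidation list went with that of the proximal tubule list and against the mitochondrial share. In AngII, library 1 had both the highest list mean (6.93) and the highest share (21.5%). In GRPR-AngII the order of the libraries followed neither measure. CDH16KO-AngII library 2 had the highest marker mean (8.93) and the lowest share (16.1%) of all libraries. Its list mean (6.30) still lay below that of every AngII and GRPR-AngII library (6.47 to 7.01), but that is 1 library. With the mitochondrial share as a covariate the median stayed at −0.52. For this covariate 0 genes were called, and 2044 had p under 0.05 against 625 by chance. The fit takes a common slope over groups that differed in how the list went with the share. It also gives the median no error between libraries, so it cannot decide about the share as the whole cause. The clock phase, log2 CPM of Dbp minus Arntl, left the median at −0.60. That covariate was tied to no more genes than chance gives (572 with p under 0.05 against 625), so the time of collection stays open. The real split gave −0.59 and the farthest from 0 among the other 9 of 10 splits 0.45 in size, and 10 splits are too few for a share under 0.05. Any deletion of the floxed gene, which the Sting1 values did not settle, may contribute. So may the presence of Cre and unrecorded differences between litters or in strain background. They were not told apart by these tests. GRPR-AngII, which carries the same Cre, had a list median of −0.12 against AngII and of 0.45 against CDH16KO-AngII. Its floxed allele differs too, so this does not set Cre apart.

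Other splits bear on the counts. For CDH16KO-AngII against AngII 1 of 10 splits, the real one, gave 21 calls and the highest other 1; for GRPR-AngII against AngII all 10 gave at least the real 0 and the highest other 1; for GRPR-AngII against CDH16KO-AngII 1 of 10, the real one, gave 18 and the highest other 0. These splits are too few for a share under 0.05. Among 100 of the 280 splits of 9 libraries into 3 groups, 2 gave at least the real 19 calls, the real one included, a share under 0.05; the highest other, 29, lay above the real count, kept the CDH16KO-AngII libraries together and mixed AngII with GRPR-AngII, and a split by replicate number gave 1. For gene lists, 10, 10 and 8 of 10 splits called at least as many as the real 2, 0 and 11, with the highest other at 18, 16 and 19, and these 10 splits too are too few for a share under 0.05.

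Genes apart in CDH16KO-AngII from both other groups often shared sequence with other genes. A partner with 95% identity over at least 50% of the transcript was found for 9 of 14 of them (64.3%) against 35 of 299 random tested genes (11.7%, Fisher exact two-sided p = 1.16e-05). The test takes the genes as independent, although Gm42429 and Gm4316 matched Gm42427, itself among them, and H2bc13 and Hist1h2bq both matched Hist1h2br. Random genes were not matched for gene type or level. Reads shared with such partners may contribute, as for Gm8730, a pseudogene that matched the ribosomal gene Rplp0 over 100%. A chromosome segment of another strain stays open: 3 loci lay within 10 Mb of another against 1.54 in random draws of tested genes (permutation test, one-sided p = 0.186). All 3 lay on chromosome 13, where 1810034E14Rik starts at 64248700, Zfp429 at 67387905 and Gm47469 at 74553910. Against AngII the first was 3.43-fold and the second 10.6-fold lower in CDH16KO-AngII, and Gm47469 was 7.87-fold higher. Fbp2, which was not among the 14, also starts on this chromosome, at 62836877. It was called against GRPR-AngII and was 1.79-fold lower in CDH16KO-AngII than in AngII without passing the threshold (edgeR adjusted p = 0.113). H2bc13 and Hist1h2bq, which are among the 14, start there at 21715763 and 21806612. The design offers a deletion of the floxed gene as a biological explanation, which was not settled and not tested apart from shared reads or a segment.

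Counts of the 2 annotated Nnt models swung between libraries, the second taking 0% to 95.8% of their sum. The coefficient of variation was 54.9% and 132% for the models and 15.2% for the sum. The coefficient of variation did not tell split reads from an allele carried by some of the mice. In libraries 1, 2 and 3 the second model took 93.5%, 95.8% and 0% in AngII. It took 34.1%, 44.0% and 0% in CDH16KO-AngII, and 0%, 19.8% and 0% in GRPR-AngII. Where it had 0 counts, the first had 3000 to 3513, which argues against reads split alike in every library. An allele was not tested, nor what it would mean for the comparisons. Without AngII library 1, which had 93.5%, no gene was called for CDH16KO-AngII against AngII.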
